A study of Homo sapiens with 4 samples.

How the data were processed

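Polyadenylated RNA was sequenced from 4 libraries of cells labelled Nalm-6, per the labels' protocols, which name a NEBNext Ultra kit that is not stated to mark strand. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.6.0 and the GRCh38 build. The aligner's options, the strand setting of the counting and the annotation release are not given in the sources used here. The authors deposited 6 tables, 1 for each pair of libraries. Per the file headers, the deposited columns hold the read count of each gene in both libraries, and these were whole numbers that did not differ between tables for the same library. The deposited normalised column equals the count divided by the library's total as RPM, with a count of 0 entered as 0.50 read. The deposited fold change is the ratio of these RPM values, named library first, and the deposited log2 column is its log2. The deposited p-value and adjusted p-value columns compare the reads of 2 single libraries, and the authors' test is not given in the sources used here. In the authors' deposited table of wild type and vector, 1185 genes were called up and 853 down. Those calls and p-values compare libraries and not conditions, and are not used further.

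The counts were joined by gene ID into 1 matrix of 25529 IDs. A gene absent from a table had 0 reads in 1 library and at most 4 in the other wherever both counts were known from other tables, and a library's count missing from all its tables was set to 0. Symbols are those of the files. Dates had replaced 21 symbols in the table of Y19D and Y19F, and these symbols were taken from the other tables or from the gene name reference. Clone-based names were not counted as symbols, and Y-linked genes and XIST were not used, which together left out 6461 IDs. Of the IDs, 25352 were found in GENCODE 29, and 95.6% had the same position there. No column of per-sample values was left unused. Library totals were 21356493 to 22072044 reads, taken from the RPM columns.

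Totals were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.998, 1.02, 1.03 and 0.96 for vector, wild type, Y19D and Y19F. Ratios are of CPM with 1 CPM added to each, and log2 ratios and medians are on that scale, which understates the difference of low genes. Folds of named genes are ratios of CPM with nothing added. Levels carry exact Poisson and ratios exact conditional binomial 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 0 reads was set against a floor of 3 counts per library and its fold written as at least that size. That size is not the bound of the 95% counting interval, which is lower (85.4-fold where ZNF618 is given as at least 106-fold) and was used to choose genes. With 1 library per group no test across samples, p-value or standard error could be had. A gene was measured where it had a symbol and a mean of at least 5 CPM in both libraries together, and counts of genes use a threshold of 2-fold. Each of 38 gene lists, with at least 5 measured members, was summarised by its median log2 ratio. The percentile is that among 10000 random lists of the same size, drawn from 20 bins of mean expression.

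The comparisons, gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, SRSF1, the 10 higher and 10 lower genes (5 and 5 for a mutant against wild type) by the bound nearest to equality of the counting interval, and up to 4 members with the largest log2 ratio of each list outside the central 95% range. Some genes under this rule are not reported here. Reads of overlapping genes cannot be told apart without strand, and near-identical copies share reads, so such genes are uncertain. Among named genes another gene with at least 20% of the reads overlaps ACAT2, ALAS2, ALDH1L2, ATF5, BEST1, CARM1, CCDC144NL-AS1, CENPA, DDIT3, EGLN3, FDPS, FEN1, FERMT3 and GINS2. The same holds for HNRNPA2B1, HNRNPAB, HSPE1, IFIT1, IFIT3, IFITM2, KRT18, KRT8, MBNL3, MT-ATP6, MT-CO3, MVK, NDUFB3 and NDUFV2, and for NOP16, PIK3CD, PSD, RPL26, RPS23, SDHD, SNRPD3, TAP1, TM7SF2, TP53INP1, WDR77, ZNF385D and ZNF385D-AS1. Near-identical copies exist for HSPA1A and HSPA1B, GYPB, U2AF1, and many histone genes. The alternatives were DESeq2 1.42.0 size factors, total counts, other expression filters, a pseudocount of 0.25 CPM, the deposited fold change, all gene IDs, means in place of medians and another fold threshold, with those added after seeing the data named with their results. Shared overlap with the single vector library was set beside 100 simulations of unchanged libraries, with counting noise and with a dispersion taken over the 4 libraries.

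The code was tested on simulated data, with 200 genes changed by known folds among 10314 measured in a simulation of wild type against vector. At a true fold of 2, 21 of 50 genes passed the 2-fold threshold, and at folds of 3 and 4 all 50 did, while 0 did at a fold of 1.5 and 0 of 10094 unchanged genes passed. The counting interval held the true ratio for 95.4% of genes. Of 200 unchanged lists in that simulation, 8 lay outside the central 95% range. Runs of neighbours were windows of 40 consecutive protein-coding genes with a mean of at least 10 CPM over the 4 libraries. A run was shifted where its median lay over 0.3 (log2) from that of all genes. Shifted runs close together and in the same direction were merged, and the median of a merged run can lie under 0.3. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.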

Results

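Messenger RNA was sequenced from cells labelled Nalm-6, a cell line derived from B-cell precursor acute lymphoblastic leukaemia, that stably carried an overexpression construct per the labels. SRSF1 is a serine and arginine rich splicing factor. The 4 libraries were labelled wild-type SRSF1, Y19D (tyrosine 19 replaced by aspartate, a negatively charged residue), Y19F (tyrosine 19 replaced by phenylalanine, which cannot be phosphorylated there) and empty vector. Each group held 1 library, so no difference below has a replicate check, and each describes 2 libraries and not 2 conditions. Intervals are exact 95% intervals that cover counting error only. The libraries held 21356493 (vector), 21672643 (wild type), 22072044 (Y19D) and 21462019 (Y19F) counted reads. Levels are given as CPM, that is read counts relative to the library total, scaled by the trimmed mean of M-values (TMM). The comparisons bear on phosphorylation of tyrosine 19, the stated subject of the series.

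SRSF1 went against the labels. The SRSF1 gene (ENSG00000136450) lies on chromosome 17 at 58003360 to 58007346 (GRCh38). Its level was highest in the library labelled empty vector, at 414 CPM (406 to 423). It was 388 CPM (379 to 396) in the library labelled Y19F, 267 CPM (261 to 274) in that labelled Y19D and 243 CPM (237 to 250.0) in that labelled wild type. The ratios to the library labelled vector were 0.588 (0.568 to 0.608) for wild type, 0.646 (0.625 to 0.667) for Y19D and 0.936 (0.908 to 0.965) for Y19F. A gene count holds reads from the cell's own gene and from a construct together, as far as the construct's sequence matches the genome. Because the gene meant to be overexpressed was lower in each library labelled as carrying it, every direction below is one between libraries named by their labels.

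**Figure D1:**
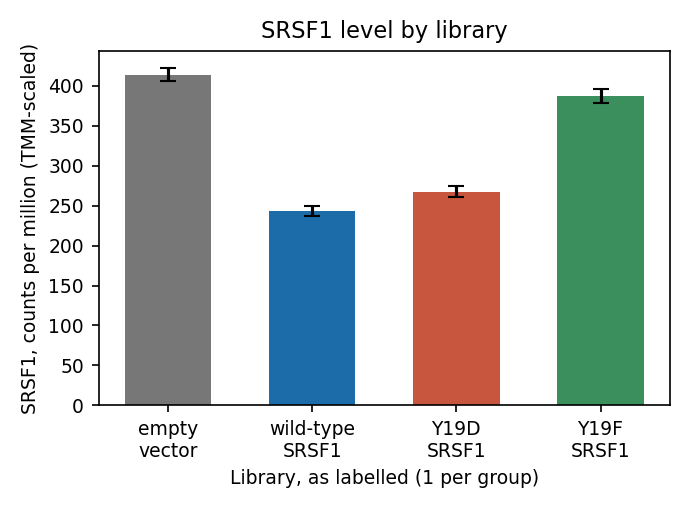
SRSF1 in each library, in TMM-scaled CPM, with exact Poisson 95% intervals (1 library per group). The library labelled empty vector stands highest at 414 CPM and that labelled wild-type SRSF1 lowest at 243 CPM.

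Many markers of the cell types did not follow the label of the line either. Of the 33 B-cell precursor markers fixed beforehand, 19 had a row in the tables. Of these, 11 were under 5 CPM in all 4 libraries and 6 were at 10 CPM or more in all 4. CD22, a surface antigen of B cells, lay at 0.563 to 1.41 CPM, and CD79A, part of the B-cell receptor, reached 0.146 CPM at most. EBF1, a transcription factor that B-cell precursors depend on, reached 0.227 CPM, while RAG1, a recombinase gene of lymphocyte precursors, lay at 5.53 to 9.25 CPM. MYB, TCF3, IKZF1, MME and LEF1, which are not restricted to B cells, were at 271 to 367 CPM, 145 to 192 CPM, 117 to 137 CPM, 41.3 to 68.5 CPM and 35.5 to 45.3 CPM. IKZF3 lay at 14.8 to 17.7 CPM and CD9 at 8.66 to 14.3 CPM. Of 27 B-cell receptor signalling genes with a row, 15 were at 10 CPM or more in all 4 libraries and 9 were under 5 CPM in all 4. Among 17 erythroid and megakaryocyte markers with a row, 7 were at 10 CPM or more in all 4 libraries and 6 were under 5 CPM in all 4. GATA1, the main erythroid transcription factor, lay at 186 to 235 CPM, embryonic globin HBE1 at 118 to 145 CPM and KLF1 at 88 to 102 CPM. The other listed globins (HBA1, HBA2, HBB, HBG1, HBG2 and HBZ) were low, at 0.291 to 6.43 CPM. The epithelial and fibroblast list had 15 members with a row, 7 at 10 CPM or more and 7 under 5 CPM in all 4 libraries. Of that list, keratins KRT8 (278 to 433 CPM) and KRT18 (80.1 to 122 CPM) and the adhesion protein EPCAM (57.2 to 112 CPM) were abundant. Fewer than 5 members of the mature B and plasma cell, T and NK cell, and myeloid lists passed the expression filter in any comparison, so these lists have no median.

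**Figure D2:**
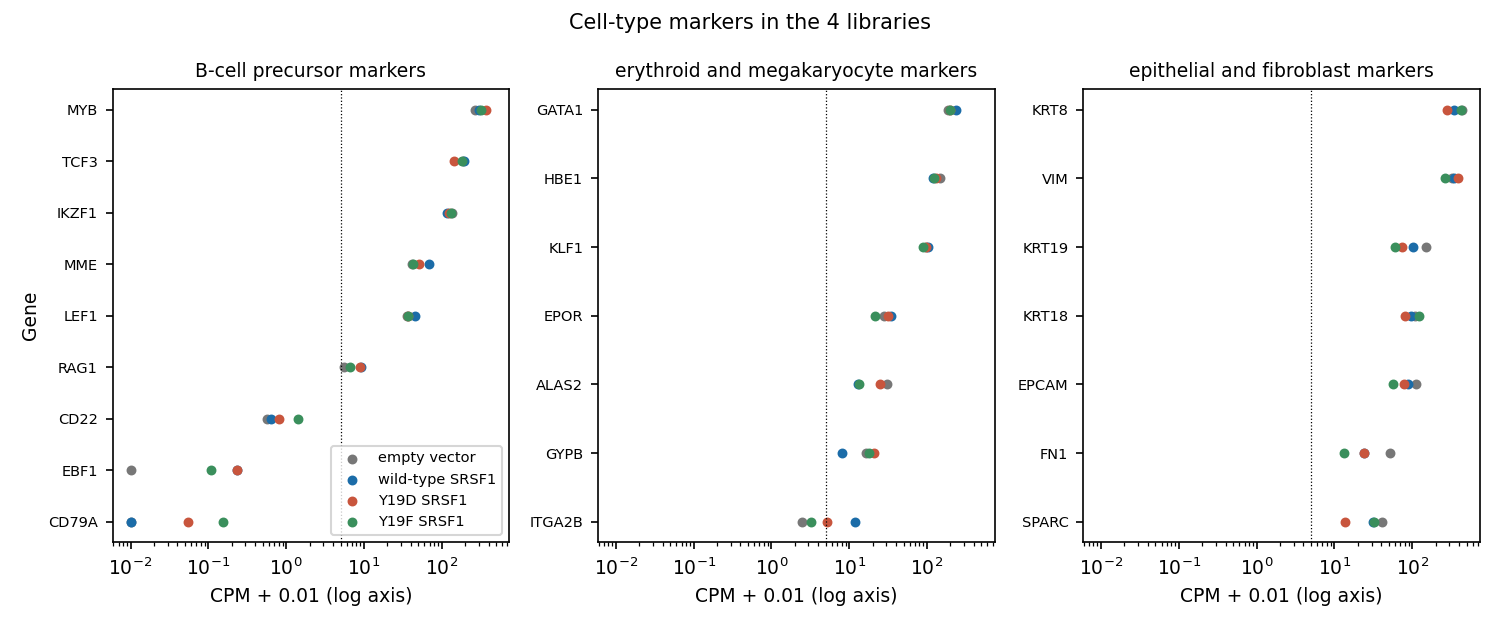
Levels of chosen members of 3 lists of cell-type markers in the 4 libraries, in CPM with 0.01 added on a log axis. Each point is 1 library and the dotted line is 5 CPM. Other members, most of them under 5 CPM in each list, are not drawn. CD22 reaches at most 1.41 CPM while GATA1 lies at 186 to 235 CPM.

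Among genes with a symbol and a mean of at least 5 CPM, the library labelled wild type had 166 genes at least 2-fold higher and 103 at least 2-fold lower than that labelled vector, of 10308 measured. The counts were 193 higher and 111 lower of 10352 for Y19D, and 71 higher and 108 lower of 10231 for Y19F. Between constructs they were 155 higher and 64 lower of 10303 for Y19D against Y19F, 111 and 97 of 10369 for Y19D against wild type, and 72 and 133 of 10260 for Y19F against wild type. These counts moved by more than 1.5 times with the expression filter, and with the fold changes of the authors' deposited table the higher count of Y19D against Y19F was 243. Of 210 medians of gene lists in the 6 comparisons, 85 lay outside the central 95% range of random lists matched on expression, where on average 10.5 would with independent genes. Genes of a pathway are regulated together, so that percentile describes these libraries and is no test. Several lists lay outside the range in the same direction in every comparison with the library labelled vector. The unfolded protein response, heat shock, MYC target and epithelial lists were lower, and the ribosomal protein, histone and antigen presentation lists higher. These comparisons share the same vector library, so part or all of that recurrence may come from it. Some lists share genes, so their medians are not separate results. SESN2 is on the p53 and ATF4 lists, DDIT4 on the ATF4 and hypoxia lists and ALDOC on the hypoxia and glycolysis lists. LDHA is on the glycolysis and MYC target lists, and HSPE1 on the MYC target and heat shock lists. Random lists did not always centre on 0, so a count of members by direction includes any shift shared by genes of like expression. In Y19D against Y19F, 51 of 54 cytosolic ribosomal protein genes were lower. Their median log2 ratio of -0.21 still lay inside the central range of -0.25 to -0.09. The lists of SR protein kinases, described SRSF1 splicing targets, nonsense-mediated decay factors, G1/S regulators, mTOR and translation initiation, NF-kB targets, B-cell precursor markers, leukaemia adhesion and homing, MAP and tyrosine kinase oncogenes and reference genes stayed inside that range in all 6 comparisons.

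**Figure D3:**
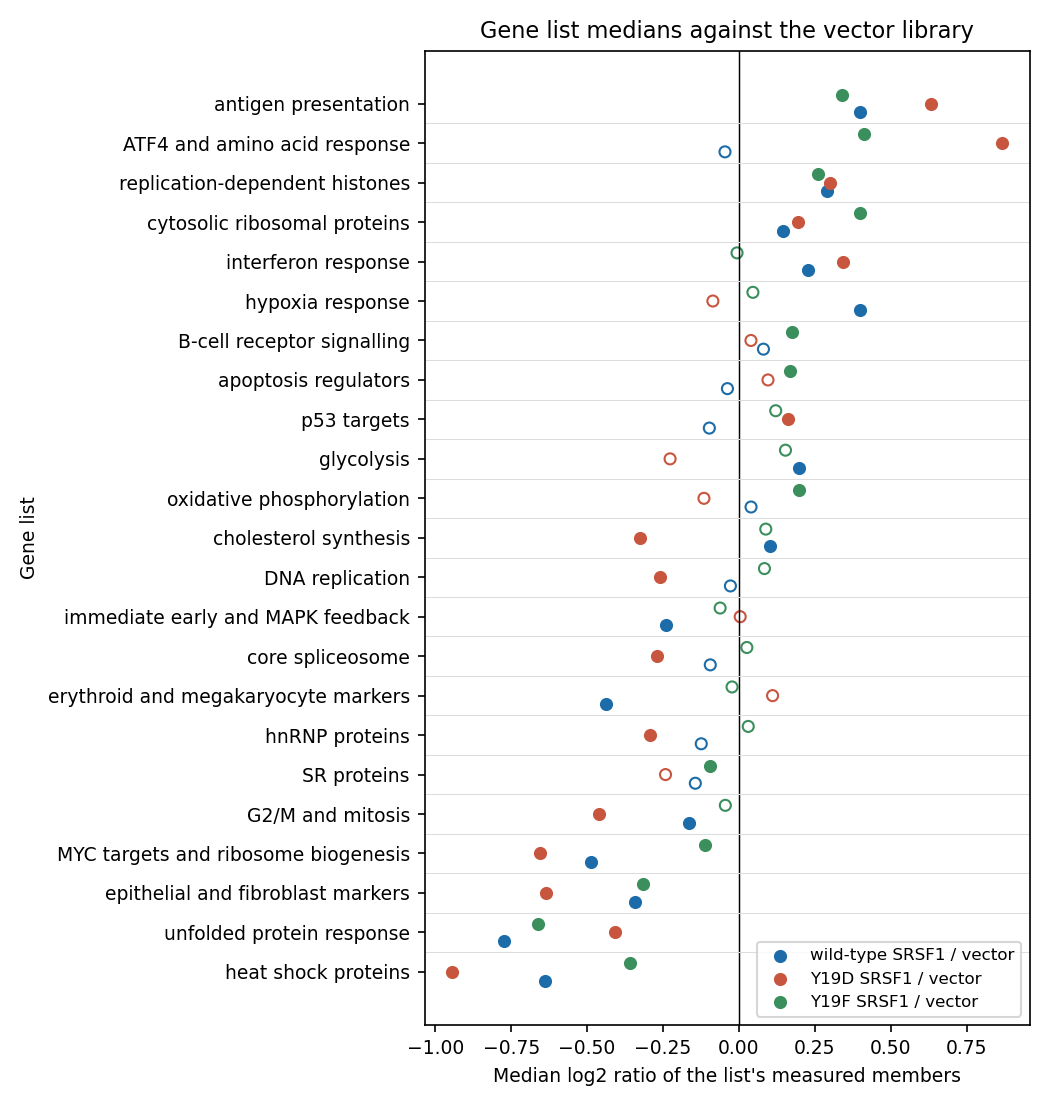
Median log2 ratio of the measured members of each list against the library labelled vector, for the lists outside the central 95% range in at least 1 of the 3 comparisons. Filled points are outside that range and open points inside, and the heat shock median of Y19D at -0.94 and its ATF4 median at 0.87 are the extremes.

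The comparison of wild type with vector asks what extra SRSF1 does, although SRSF1 itself was 1.7-fold lower in the library labelled wild type. The unfolded protein response and heat shock lists were lower there, while hypoxia, glycolysis, interferon and antigen presentation genes were higher. All 21 measured members of the unfolded protein response list were lower (median log2 ratio -0.77, below all 10000 random lists). HSPA5, the main chaperone of the endoplasmic reticulum, was 3.93-fold lower (interval 3.84 to 4.03) and MANF, HSP90B1 and HYOU1 were 3.24-fold, 2.62-fold and 2.08-fold lower. Of the heat shock proteins, 15 of 16 were lower (median log2 ratio -0.64, below all 10000 random lists). HSPA1A, an inducible HSP70 with a near-identical copy in HSPA1B, was 3.61-fold lower (interval 3.32 to 3.92) and HSPA1B, HSPH1 and BAG3 were 3.15-fold, 1.97-fold and 1.99-fold lower. Of the MYC target and ribosome biogenesis genes, 32 of 35 were lower (median log2 ratio -0.49, below all 10000 random lists). NOP16 was 2.14-fold lower (interval 1.91 to 2.39) and UTP20, NOP56 and WDR43 were 1.95-fold, 1.86-fold and 1.75-fold lower. The immediate early list had 13 of 18 members lower (median log2 ratio -0.24, at percentile 0.98). FOS, a subunit of the AP-1 transcription factor, was 3.65-fold lower (interval 2.73 to 4.95) and EGR1, JUN and ATF3 were 2.9-fold, 2.72-fold and 1.68-fold lower. G2/M genes were lower for 28 of 39 (median log2 ratio -0.16, at percentile 2.35). CDC20 was 1.53-fold lower (interval 1.45 to 1.62) and PLK1, CCNB1 and CCNF were 1.53-fold, 1.48-fold and 1.37-fold lower.

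Hypoxia response genes were higher for 14 of 19 in the library labelled wild type (median log2 ratio 0.40, above all 10000 random lists). PFKFB4, a regulator of glycolytic flux, was 2.39-fold higher (interval 2.16 to 2.64) and ALDOC, DDIT4 and PDK1 were 2.3-fold, 1.88-fold and 1.76-fold higher. Glycolysis genes were higher for 13 of 20 (median log2 ratio 0.20, at percentile 99.9). ALDOC was 2.3-fold higher (interval 2.09 to 2.53), SLC2A3 and ENO2 were 1.65-fold and 1.48-fold higher and SLC16A1 was 1.64-fold lower. Interferon response genes were higher for 12 of 18 (median log2 ratio 0.23, at percentile 98.8). IFITM2 was 4.73-fold higher (interval 3.71 to 6.09) and IFIH1, IFIT3 and IFIT1 were 3.76-fold, 3.31-fold and 3.15-fold higher. All 5 measured antigen presentation genes were higher (median log2 ratio 0.40, at percentile 99.4). HLA-E was 2.68-fold higher (interval 2.47 to 2.91) and TAP1, TAPBP and B2M were 2.0-fold, 1.32-fold and 1.14-fold higher. Cholesterol synthesis genes were higher for 14 of 24 (median log2 ratio 0.10, at percentile 98.1). SQLE, squalene epoxidase, was 1.8-fold higher (interval 1.74 to 1.86) and TM7SF2 and HSD17B7 were 1.38-fold and 1.32-fold higher. Cytosolic ribosomal protein genes were higher for 51 of 54 (median log2 ratio 0.15, above all 10000 random lists). RPL26 was 1.88-fold lower (interval 1.46 to 2.45) and RPL22, RPL3 and RPS3 were 1.39-fold, 1.33-fold and 1.27-fold higher. Replication-dependent histone genes, counted here in polyadenylated RNA only, were higher for 7 of 11 (median log2 ratio 0.29, at percentile 99.4). HIST1H3B was 2.23-fold higher (interval 1.87 to 2.68) and HIST1H2AE, HIST2H2BE and HIST1H3H were 1.43-fold, 1.32-fold and 1.26-fold higher. Erythroid and megakaryocyte markers were lower for 6 of 10 (median log2 ratio -0.44, at percentile 0.010). ITGA2B, the megakaryocyte integrin, was 4.93-fold higher (interval 3.65 to 6.77) and ALAS2 and GYPB were 2.36-fold and 2.03-fold lower. Epithelial and fibroblast markers were lower for 6 of 7 (median log2 ratio -0.34, at percentile 0.885). FN1, fibronectin, was 2.15-fold lower (interval 1.93 to 2.39) and KRT19, SPARC and EPCAM were 1.45-fold, 1.29-fold and 1.27-fold lower. Inside the central 95% range lay the medians of cholesterol synthesis, erythroid markers and histones with means in place of medians, of antigen presentation and interferon response at a mean of 1 CPM or more, and of interferon response without chromosomes 2, 9 and 10.

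The single genes with the largest lower bounds of their ratio to the library labelled vector were led by MYCT1, which was 95.7-fold higher (interval 32.4 to 467, 13.5 against 0.141 CPM) and FSTL5, a follistatin-like secreted protein, was 21.3-fold higher (interval 14.5 to 32.6, 26.9 against 1.27 CPM). GRB14, FEV, NRCAM and GBP4 were 23.9-fold, 23.1-fold, 12.7-fold and 16.1-fold higher. HTR7, ASB9, SOD1P3 and IGSF10 were 15.5-fold, 14.5-fold, 9.28-fold and 9.74-fold higher. TMPRSS15, the gene of enteropeptidase, was 91.4-fold lower (interval 44.1 to 228, 0.317 against 29 CPM), and MAGEC1, a cancer-testis antigen, was 16.4-fold lower (interval 13.2 to 20.6, 3.99 against 65.4 CPM). MUC19, CCDC144NL-AS1, TSPAN5 and SCIN were 13.7-fold, 16.4-fold, 14.1-fold and 9.38-fold lower. ADAM19, SYNE2, KIAA0040 and IL10RA were 8.78-fold, 7.67-fold, 8.81-fold and 6.58-fold lower. CCDC144NL-AS1 overlaps USP22, and SOD1P3 is a processed pseudogene, so their counts are uncertain.

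The library labelled Y19D, a replacement by a charged residue, had SRSF1 1.55-fold lower than that labelled vector. Amino acid response genes were higher, and heat shock, ribosome biogenesis, G2/M, core spliceosome and cholesterol synthesis genes were lower. All 27 measured members of the ATF4 and amino acid response list were higher (median log2 ratio 0.87, above all 10000 random lists), and 10 of them at least 2-fold. DDIT4, an inhibitor of mTOR, was 3.31-fold higher (interval 3.09 to 3.55) and ATF5, PCK2 and ALDH1L2 were 2.5-fold, 2.43-fold and 2.33-fold higher. Of the heat shock proteins, 15 of 16 were lower (median log2 ratio -0.94, below all 10000 random lists). HSPH1, an HSP110 chaperone, was 3.1-fold lower (interval 2.95 to 3.26) and HSPA1A, CHORDC1 and HSPA8 were 3.07-fold, 2.86-fold and 2.72-fold lower. MYC targets and ribosome biogenesis genes were lower for 34 of 35 (median log2 ratio -0.66, below all 10000 random lists). UTP20 was 2.24-fold lower (interval 2.1 to 2.39) and NOP16, RRS1 and RRP9 were 2.21-fold, 2.22-fold and 2.12-fold lower. The unfolded protein response list was lower for 16 of 21 (median log2 ratio -0.41, at percentile 0.020). MANF was 3.06-fold lower (interval 2.68 to 3.5) and HSP90B1, HSPA5 and SDF2L1 were 2.67-fold, 2.6-fold and 2.46-fold lower.

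The library labelled Y19D had 37 of 39 G2/M genes lower (median log2 ratio -0.46, below all 10000 random lists). PLK1, a mitotic kinase, was 1.98-fold lower (interval 1.86 to 2.11) and CDC20, CCNB1 and CCNF were 1.93-fold, 1.9-fold and 1.7-fold lower. DNA replication genes were lower for 31 of 39 (median log2 ratio -0.26, at percentile 0.255). FEN1 was 1.71-fold lower (interval 1.62 to 1.8) and CDC6, GINS2 and MCM10 were 1.49-fold, 1.49-fold and 1.48-fold lower. Core spliceosome genes were lower for 40 of 44 (median log2 ratio -0.27, at percentile 0.030). PRPF4 was 1.65-fold lower (interval 1.54 to 1.77) and PRPF3, U2AF2 and PRPF31 were 1.62-fold, 1.56-fold and 1.57-fold lower. The hnRNP genes were lower for 23 of 26 (median log2 ratio -0.29, at percentile 0.31). HNRNPM was 1.64-fold lower (interval 1.59 to 1.69) and SYNCRIP, HNRNPU and HNRNPAB were 1.64-fold, 1.52-fold and 1.49-fold lower. Cholesterol synthesis genes were lower for 19 of 24 (median log2 ratio -0.33, at percentile 0.050). TM7SF2 was 1.91-fold higher (interval 1.6 to 2.27) and DHCR7 and ACAT2 were 1.59-fold and 1.59-fold lower. Epithelial and fibroblast markers were lower for 6 of 7 (median log2 ratio -0.64, below all 10000 random lists). SPARC was 2.97-fold lower (interval 2.61 to 3.4) and FN1, KRT19 and KRT8 were 2.15-fold, 2.03-fold and 1.56-fold lower.

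Ribosomal protein genes were higher for 47 of 54 in the library labelled Y19D (median log2 ratio 0.19, above all 10000 random lists). RPL26 was 1.68-fold lower (interval 1.32 to 2.16) and RPL22, RPL3 and RPL12 were 1.48-fold, 1.39-fold and 1.36-fold higher. Replication-dependent histone genes, counted in polyadenylated RNA only, were higher for 11 of 12 (median log2 ratio 0.30, at percentile 99.5). HIST1H1D was 2.34-fold higher (interval 1.74 to 3.18) and HIST1H3B, HIST2H2BE and HIST1H4H were 1.63-fold, 1.5-fold and 1.36-fold higher. Interferon response genes were higher for 11 of 17 (median log2 ratio 0.34, at percentile 99.7). IFITM3 was 1.76-fold higher (interval 1.62 to 1.92), IFITM2 and STAT2 were 1.87-fold and 1.42-fold higher and OAS3 was 1.87-fold lower. All 5 antigen presentation genes were higher (median log2 ratio 0.63, at percentile 99.9). HLA-E was 1.91-fold higher (interval 1.75 to 2.08) and TAP1, TAPBP and TAP2 were 1.9-fold, 1.56-fold and 1.06-fold higher, the last with an interval that held 1. Targets of p53 were higher for 12 of 20 (median log2 ratio 0.16, at percentile 98.7). SESN2 was 1.83-fold higher (interval 1.73 to 1.94), TP53INP1 was 1.71-fold higher and BTG2 and TRIAP1 were 1.84-fold and 1.63-fold lower. Inside the central 95% range lay the medians of interferon response and p53 targets with means in place of medians, and of interferon response and p53 targets at a mean of 1 CPM or more.

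Of single genes, HCLS1, a signalling adaptor of blood cells, was 22-fold higher (interval 11.8 to 46.6, 10.3 against 0.469 CPM) in the library labelled Y19D. MLLT3, a subunit of a transcription elongation complex, was 12.7-fold higher (interval 9.41 to 17.7, 26.9 against 2.11 CPM). RHOBTB1, HTR7, SOD1P3 and LINC00861 were 15-fold, 14.8-fold, 9.61-fold and 7.11-fold higher. THBS1, BCHE, SLIT2 and INPP4B were 7.11-fold, 8.74-fold, 6.77-fold and 7.59-fold higher. MBNL3, a regulator of splicing, was 39-fold lower (interval 18.6 to 97.9, 0.309 against 12.1 CPM), but it overlaps RAP2C-AS1. MUC19, TMPRSS15, KIAA0040 and MAGEC1 were 12-fold, 12.6-fold, 11.6-fold and 7.83-fold lower. EPHB6, KAZN, BEST1, DHRS2 and NEFH were 9.39-fold, 8.44-fold, 6.17-fold, 5.78-fold and 5.11-fold lower, and BEST1 overlaps FTH1, the abundant ferritin heavy chain gene.

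In the library labelled Y19F, a replacement without a charge, SRSF1 was 1.07-fold lower than in that labelled vector, the smallest such difference. Ribosomal protein, oxidative phosphorylation and amino acid response genes were higher, and the unfolded protein response and heat shock lists lower. Ribosomal protein genes were higher for 53 of 54 (median log2 ratio 0.40, above all 10000 random lists). RPL22 was 1.57-fold higher (interval 1.53 to 1.61) and RPL32, RPL3 and RPS24 were 1.54-fold, 1.49-fold and 1.48-fold higher. Oxidative phosphorylation genes were higher for 35 of 36 (median log2 ratio 0.20, above all 10000 random lists). NDUFV2 was 1.88-fold higher (interval 1.47 to 2.43) and COX7A2, CYC1 and NDUFB3 were 1.37-fold, 1.32-fold and 1.32-fold higher. The ATF4 and amino acid response list was higher for 26 of 27 (median log2 ratio 0.41, above all 10000 random lists). PSAT1, an enzyme of serine synthesis, was 2.42-fold higher (interval 2.33 to 2.51) and DDIT4, CHAC1 and ASNS were 2.23-fold, 2.19-fold and 1.93-fold higher. The unfolded protein response list was lower for 20 of 21 (median log2 ratio -0.66, below all 10000 random lists). HSPA5 was 2.85-fold lower (interval 2.78 to 2.91) and MANF, HSP90B1 and PDIA4 were 2.78-fold, 2.52-fold and 2.28-fold lower. Heat shock proteins were lower for 14 of 16 (median log2 ratio -0.36, below all 10000 random lists). HSPA1A was 2.27-fold lower (interval 2.11 to 2.44) and HSPA1B, HSPA8 and CHORDC1 were 1.89-fold, 1.85-fold and 1.64-fold lower. MYC targets and ribosome biogenesis genes were lower for 29 of 35 (median log2 ratio -0.11, at percentile 0.080). RRS1 was 1.53-fold lower (interval 1.36 to 1.73) and UTP20, WDR43 and NOP16 were 1.51-fold, 1.4-fold and 1.33-fold lower.

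Replication-dependent histone genes, counted in polyadenylated RNA only, were higher for 9 of 11 in the library labelled Y19F (median log2 ratio 0.26, at percentile 99.2). HIST1H3B was 1.59-fold higher (interval 1.31 to 1.93) and HIST2H2BE, HIST1H2BC and HIST1H2AE were 1.46-fold, 1.4-fold and 1.29-fold higher. Apoptosis regulators were higher for 15 of 22 (median log2 ratio 0.17, at percentile 99.2). CASP8, an initiator caspase, was 1.65-fold lower (interval 1.44 to 1.88) and BCL2, BAX and BCL2L1 were 1.45-fold, 1.33-fold and 1.26-fold higher. B-cell receptor signalling genes, most of them shared with other blood cells, were higher for 13 of 17 (median log2 ratio 0.17, at percentile 98.8). SH3BP2 was 3.3-fold higher (interval 2.81 to 3.88) and PLCG2, VAV2 and PIK3CD were 2.04-fold, 1.8-fold and 1.38-fold higher. Antigen presentation genes were higher for 4 of 5 (median log2 ratio 0.34, at percentile 99.1). TAP1 was 1.5-fold higher (interval 1.27 to 1.79), HLA-E and TAP2 were 1.32-fold and 1.27-fold higher and B2M was 1.07-fold lower. SR proteins were lower for 10 of 15 (median log2 ratio -0.10, at percentile 1.67). TRA2A was 1.26-fold lower (interval 1.18 to 1.35), SRSF5 and SRRM1 were 1.18-fold and 1.12-fold higher and SRSF6 was 1.21-fold lower. Epithelial and fibroblast markers were lower for 6 of 7 (median log2 ratio -0.32, at percentile 0.060). FN1 was 3.88-fold lower (interval 3.4 to 4.45) and KRT19, EPCAM and SPARC were 2.48-fold, 1.96-fold and 1.25-fold lower. Inside the central 95% range lay the medians of SR proteins, antigen presentation and apoptosis regulators with means in place of medians, of antigen presentation and apoptosis regulators at a mean of 1 CPM or more, and of histones against lists matched on transcript length too.

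Single genes lower in the library labelled Y19F had few reads there. MUC19 had 1 read against 1714, and was 1656-fold lower with an interval of 297 to 65462. ADAM19, EPHB6, ANO5 and MBNL3 were 72.5-fold, 111-fold, 111-fold and 82.8-fold lower. KIAA0040, CCDC26 and SCIN were 74.1-fold, 59.9-fold and 40.9-fold lower. The neighbouring genes MS4A4A and MS4A3 were 34.1-fold and 35.7-fold lower. The cell adhesion gene NRCAM was 6.53-fold higher (interval 5.11 to 8.44, 23 against 3.52 CPM), and DTNA, MLLT3 and OSBPL1A were 6.73-fold, 5.36-fold and 4.87-fold higher. FERMT3, FCGR2A and SUSD3 were 3.64-fold, 3.71-fold and 3.78-fold higher, and MUC4, PSD and GAD1 were 3.44-fold, 3.66-fold and 3.5-fold higher. FERMT3 overlaps TRPT1 and PSD overlaps FBXL15. PSD, RPS24 and GAD1 lie in runs of neighbouring genes that were higher together in this library.

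Y19D against Y19F compares libraries labelled with the charged and the uncharged replacement, whose SRSF1 differed 1.45-fold, lower in that labelled Y19D. Ribosome biogenesis, heat shock, G2/M, DNA replication, core spliceosome and cholesterol synthesis lists were lower in the library labelled Y19D, and the ATF4 and unfolded protein response lists were higher. All 35 MYC target and ribosome biogenesis genes were lower (median log2 ratio -0.54, below all 10000 random lists). NOLC1, a nucleolar protein, was 2.06-fold lower (interval 2.0 to 2.12) and NME1, SRM and RRP9 were 2.06-fold, 1.68-fold and 1.68-fold lower. All 16 heat shock proteins were lower (median log2 ratio -0.55, below all 10000 random lists). HSPH1 was 2.08-fold lower (interval 1.98 to 2.2) and HSP90AA1, BAG3 and DNAJA1 were 1.94-fold, 1.88-fold and 1.77-fold lower. G2/M genes were lower for 37 of 39 (median log2 ratio -0.42, below all 10000 random lists). MKI67, the proliferation marker, was 1.97-fold lower (interval 1.9 to 2.03) and PTTG1, CDC20 and CCNB1 were 1.74-fold, 1.7-fold and 1.66-fold lower. DNA replication genes were lower for 37 of 39 (median log2 ratio -0.34, below all 10000 random lists). FEN1 was 1.67-fold lower (interval 1.58 to 1.76) and MCM6, MCM4 and GINS2 were 1.62-fold, 1.59-fold and 1.53-fold lower. Core spliceosome genes were lower for 43 of 44 (median log2 ratio -0.35, below all 10000 random lists). The central range of those random lists ran from -0.21 to -0.002. SF3B5 was 1.8-fold lower (interval 1.67 to 1.93) and PRPF3, PRPF4 and SNRPD3 were 1.73-fold, 1.7-fold and 1.58-fold lower. Genes of hnRNP proteins were lower for 24 of 26 (median log2 ratio -0.34, at percentile 0.21). HNRNPH2 was 1.6-fold lower (interval 1.49 to 1.71) and HNRNPAB, HNRNPA2B1 and HNRNPK were 1.47-fold, 1.44-fold and 1.42-fold lower. Arginine methyltransferases were lower for 7 of 9 (median log2 ratio -0.32, at percentile 1.66). PRMT1, the main enzyme of the group, was 1.42-fold lower (interval 1.35 to 1.49) and WDR77, CARM1 and PRMT7 were 1.41-fold, 1.33-fold and 1.3-fold lower. NOLC1, MKI67, BAG3 and PGAM1 on chromosome 10, HNRNPK on chromosome 9, and FDPS and IFI16 on chromosome 1 lie in runs of neighbours whose median was lower in the library labelled Y19D than in that labelled Y19F, though IFI16 was higher.

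Cholesterol synthesis was lower for 21 of 24 in the library labelled Y19D (median log2 ratio -0.43, at percentile 0.010). FDPS was 2.05-fold lower (interval 1.88 to 2.24) and DHCR7, MVK and EBP were 1.69-fold, 1.7-fold and 1.61-fold lower. Glycolysis was lower for 18 of 20 (median log2 ratio -0.36, at percentile 0.25). PGAM1 was 2.04-fold lower (interval 1.96 to 2.12) and PGK1, LDHA and HK2 were 1.69-fold, 1.59-fold and 1.49-fold lower. Oxidative phosphorylation was lower for 34 of 36 (median log2 ratio -0.30, at percentile 0.070). COX7B was 1.6-fold lower (interval 1.5 to 1.7) and UQCRQ, NDUFA4 and SDHB were 1.63-fold, 1.55-fold and 1.47-fold lower. Mitochondrially encoded genes had a median log2 ratio of -0.01, at percentile 98 of random lists whose central range ran from -0.34 to -0.02, and it was 0.09, of the other sign, with total counts. MT-ND2 was 1.31-fold lower (interval 1.3 to 1.32) and MT-ND1, MT-ND5 and MT-ND6 were 1.28-fold, 1.15-fold and 1.13-fold lower. The ATF4 and amino acid response list was higher for 22 of 27 (median log2 ratio 0.27, above all 10000 random lists). ATF5, a stress transcription factor, was 3.35-fold higher (interval 3.01 to 3.74) and TRIB3, ALDH1L2 and SESN2 were 1.92-fold, 1.74-fold and 1.6-fold higher. The unfolded protein response list was higher for 17 of 21 (median log2 ratio 0.19, at percentile 100). DDIT3, the stress factor CHOP, was 2.05-fold higher (interval 1.74 to 2.42), PPP1R15A and SEL1L were 1.95-fold and 1.44-fold higher and SDF2L1 was 1.53-fold lower. Antigen presentation was higher for 4 of 5 (median log2 ratio 0.32, at percentile 99.1). TAPBP was 1.49-fold higher (interval 1.4 to 1.59), HLA-E and TAP1 were 1.45-fold and 1.26-fold higher and TAP2 was 1.2-fold lower. Erythroid markers were higher for 6 of 8 (median log2 ratio 0.17, at percentile 97.6). ALAS2 was 1.87-fold higher (interval 1.61 to 2.17) and EPOR and GYPB were 1.45-fold and 1.17-fold higher. Epithelial and fibroblast markers had a median of 0.29 (at percentile 99.7) and a mean of -0.039, of the other sign. SPARC was 2.38-fold lower (interval 2.07 to 2.73), FN1 was 1.81-fold higher and KRT18 and KRT8 were 1.52-fold and 1.51-fold lower. Inside the central 95% range lay the medians of methyltransferases, epithelial markers and mitochondrial genes with means in place of medians, of epithelial markers, erythroid markers and mitochondrial genes at a mean of 1 CPM or more, of erythroid markers with 0.25 CPM added, and of erythroid markers and mitochondrial genes without chromosomes 2, 9 and 10.

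Of single genes, ZNF618 had no read in the library labelled Y19F. It was at least 106-fold higher (15.4 against 0 CPM) in that labelled Y19D, against a floor of 3 counts, with a lower interval bound of 85.4. The receptor tyrosine kinase gene KIT was 54.3-fold higher (interval 23 to 168, 13.2 against 0.243 CPM). SLITRK6, MS4A4A, HCLS1 and PPFIBP2 were 237.6-fold, 21.7-fold, 26.6-fold and 22.4-fold higher, the first of these against 1 read with an interval of 42.3 to 9421. MS4A3, IFI16, AFAP1-AS1 and RGS18 were 16-fold, 11.3-fold, 7.95-fold and 7.5-fold higher. MAGEC1 was 9.82-fold lower (interval 8.45 to 11.5, 8.35 against 82 CPM). PDK3, LHFPL2, UBASH3B and TMPRSS15 were 11.4-fold, 9.54-fold, 8.29-fold and 7.84-fold lower. SH3GL3, LINC00665, GAD1, PM20D2 and IGSF10 were 6.17-fold, 6.92-fold, 5.5-fold, 5.33-fold and 6.14-fold lower.

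Against wild type, the library labelled Y19D had SRSF1 1.1-fold higher, the smallest SRSF1 difference between constructs. Amino acid response genes were higher, and cholesterol synthesis, glycolysis, hypoxia, G2/M and DNA replication genes lower. All 27 ATF4 and amino acid response genes were higher (median log2 ratio 0.72, above all 10000 random lists). ALDH1L2, a mitochondrial enzyme of folate metabolism, was 4.55-fold higher (interval 4.21 to 4.93) and ATF5, SLC7A5 and CHAC1 were 3.04-fold, 2.55-fold and 2.53-fold higher. The unfolded protein response list was higher for 17 of 21 (median log2 ratio 0.29, above all 10000 random lists). DDIT3 was 1.73-fold higher (interval 1.49 to 2.01) and PPP1R15A, HSPA5 and XBP1 were 1.54-fold, 1.51-fold and 1.51-fold higher. Cholesterol synthesis was lower for 22 of 24 (median log2 ratio -0.42, below all 10000 random lists). HSD17B7 was 1.82-fold lower (interval 1.62 to 2.05) and MVK, SQLE and FDPS were 1.76-fold, 1.65-fold and 1.63-fold lower. Glycolysis was lower for 18 of 20 (median log2 ratio -0.37, below all 10000 random lists). LDHA, lactate dehydrogenase A, was 1.7-fold lower (interval 1.68 to 1.73) and PGK1, PKM and ALDOC were 1.68-fold, 1.61-fold and 1.51-fold lower. Hypoxia response was lower for 15 of 19 (median log2 ratio -0.35, below all 10000 random lists). NDRG1 was 6.24-fold lower (interval 4.63 to 8.56), DDIT4 was 1.76-fold higher and PFKFB4 and PDK1 were 2.37-fold and 1.83-fold lower. G2/M genes were lower for 38 of 39 (median log2 ratio -0.30, below all 10000 random lists). BUB1 was 1.61-fold lower (interval 1.55 to 1.68) and CENPA, CDK1 and MKI67 were 1.45-fold, 1.39-fold and 1.38-fold lower. DNA replication was lower for 33 of 39 (median log2 ratio -0.22, at percentile 0.010). FEN1 was 1.49-fold lower (interval 1.4 to 1.57), RRM2 was 1.37-fold higher and POLE2 and LIG1 were 1.35-fold and 1.32-fold lower. PDK1, HNRNPA3 and GRB14 lie in a run on chromosome 2 that was lower, and RRM2 and RPS7 in another that was higher, in the library labelled Y19D.

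Against wild type, 40 of 43 core spliceosome genes were also lower in the library labelled Y19D (median log2 ratio -0.18, at percentile 0.020). SF3B5 was 1.58-fold lower (interval 1.46 to 1.7) and PRPF31, SNRPD1 and PRPF3 were 1.41-fold, 1.36-fold and 1.34-fold lower. Genes of hnRNP proteins were lower for 23 of 26 (median log2 ratio -0.18, at percentile 0.11). HNRNPA3 was 1.4-fold lower (interval 1.37 to 1.43), PTBP3 was 1.28-fold higher and HNRNPDL and HNRNPH2 were 1.31-fold and 1.31-fold lower. MYC targets were lower for 27 of 35 (median log2 ratio -0.18, at percentile 0.030). LDHA was 1.7-fold lower (interval 1.68 to 1.73), MYC was 1.34-fold higher and TFRC and GAR1 were 1.4-fold and 1.33-fold lower. Heat shock proteins were lower for 12 of 16 (median log2 ratio -0.16, at percentile 1.63). CHORDC1 was 1.87-fold lower (interval 1.76 to 1.98) and HSPA8, HSPH1 and DNAJA1 were 1.72-fold, 1.58-fold and 1.43-fold lower. Oxidative phosphorylation was lower for 32 of 36 (median log2 ratio -0.13, at percentile 0.83). NDUFV2 was 1.5-fold lower (interval 1.2 to 1.88) and COX5B, SDHB and SDHD were 1.32-fold, 1.26-fold and 1.25-fold lower. Epithelial and fibroblast markers were lower for 5 of 7 (median log2 ratio -0.28, at percentile 0.525). SPARC was 2.31-fold lower (interval 2.02 to 2.65) and KRT19, KRT8 and KRT18 were 1.4-fold, 1.24-fold and 1.22-fold lower. Targets of p53 were higher for 12 of 20 (median log2 ratio 0.14, at percentile 99.5). SESN2 was 2.14-fold higher (interval 2.02 to 2.27), CDKN1A and PMAIP1 were 2.14-fold and 1.68-fold higher and ZMAT3 was 1.53-fold lower. Mitochondrially encoded genes were higher for 10 of 12 (median log2 ratio 0.24, at percentile 100). MT-ATP6 was 1.25-fold higher (interval 1.24 to 1.26) and MT-CYB, MT-CO2 and MT-CO3 were 1.22-fold, 1.22-fold and 1.21-fold higher. Ribosomal proteins were higher for 36 of 53 (median log2 ratio 0.04, at percentile 97.9). RPS23 was 1.29-fold lower (interval 1.16 to 1.45) and RPS7, RPL12 and RPL10A were 1.25-fold, 1.19-fold and 1.17-fold higher. Inside the central 95% range lay the medians of ribosomal proteins with means in place of medians, of ribosomal proteins without chromosomes 2, 9 and 10, and of heat shock proteins and oxidative phosphorylation against lists matched on transcript length too.

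Of single genes, SLITRK6 had no read in the library labelled wild type. It was at least 84.8-fold higher (11.5 against 0 CPM) in that labelled Y19D against a floor of 3 counts, with a lower interval bound of 68.4. HCLS1, MLLT3, RHOBTB1 and TRDN were 228-fold, 53.9-fold, 54.4-fold and 33.7-fold higher, HCLS1 against 1 read with an interval of 40.5 to 9042. GRB14 and MYCT1 had no read in the library labelled Y19D. They were at least 118-fold and at least 102-fold lower against a floor of 3 counts, with lower interval bounds of 95.8 and 82.1. FSTL5, GBP4 and ZNF385D were 122-fold, 128-fold and 58.9-fold lower, GBP4 with 2 reads with an interval of 35 to 1061. ZNF385D overlaps its antisense gene, so its reads cannot be assigned to a strand.

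Against wild type, the library labelled Y19F had SRSF1 1.59-fold higher. The ribosome biogenesis, amino acid response and heat shock lists were higher there, and the interferon, antigen presentation and hypoxia lists lower. The unfolded protein response list lay inside the central range. MYC targets and ribosome biogenesis genes were higher for 33 of 35 (median log2 ratio 0.35, above all 10000 random lists). NOLC1 was 1.87-fold higher (interval 1.82 to 1.93) and NOP16, ODC1 and MYC were 1.61-fold, 1.57-fold and 1.53-fold higher. The ATF4 and amino acid response list was higher for 26 of 27 (median log2 ratio 0.33, above all 10000 random lists). ALDH1L2 was 2.61-fold higher (interval 2.4 to 2.84) and SLC7A5, CHAC1 and PSAT1 were 2.54-fold, 2.35-fold and 1.75-fold higher. Heat shock proteins were higher for 13 of 16 (median log2 ratio 0.29, at percentile 99.8). BAG3 was 1.97-fold higher (interval 1.77 to 2.18) and HSPA1B, HSPA1A and HSPE1 were 1.66-fold, 1.59-fold and 1.58-fold higher. Ribosomal proteins were higher for 53 of 54 (median log2 ratio 0.25, at percentile 100). Random lists matched to them were higher too, with a central range of 0.09 to 0.21. RPL26 was 1.89-fold higher (interval 1.46 to 2.46), RPL35 and RPS24 were 1.55-fold and 1.41-fold higher and RPS23 was 1.43-fold lower. Oxidative phosphorylation was higher for 30 of 37 (median log2 ratio 0.18, at percentile 99.3). NDUFA4 was 1.45-fold higher (interval 1.36 to 1.54) and COX7B, UQCRQ and NDUFB3 were 1.4-fold, 1.37-fold and 1.34-fold higher. Core spliceosome genes were higher for 40 of 44 (median log2 ratio 0.17, at percentile 98.3). PRPF4 was 1.5-fold higher (interval 1.4 to 1.6) and U2AF1, SNRPC and SF3B4 were 1.55-fold, 1.37-fold and 1.3-fold higher. Arginine methyltransferases were higher for 8 of 9 (median log2 ratio 0.27, at percentile 98.9). PRMT6 was 1.59-fold higher (interval 1.45 to 1.74) and PRMT7, WDR77 and PRMT3 were 1.35-fold, 1.28-fold and 1.22-fold higher. NOLC1, RPS24, BAG3, PGAM1, IFIT1 and IFIT3 on chromosome 10 and RPL35 and PSAT1 on chromosome 9 lie in runs of neighbours. The medians of these runs were higher in the library labelled Y19F, though IFIT1 and IFIT3 were lower there.

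Interferon response genes were lower for 11 of 18 in the library labelled Y19F (median log2 ratio -0.22, at percentile 0.57). IFIT3 was 12.1-fold lower (interval 7.71 to 20.2) and IFIT1, IFIH1 and IFITM2 were 10.8-fold, 4.07-fold and 1.85-fold lower. IFIT1 and IFIT3 overlap LIPA, so their counts are uncertain. Antigen presentation was lower for 4 of 5 (median log2 ratio -0.34, at percentile 0.24). HLA-E was 2.04-fold lower (interval 1.89 to 2.2) and TAP1, TAPBP and B2M were 1.33-fold, 1.27-fold and 1.22-fold lower. Hypoxia response was lower for 11 of 19 (median log2 ratio -0.21, at percentile 0.010). PFKFB4 was 2.45-fold lower (interval 2.22 to 2.71), EGLN3 was 1.83-fold higher and P4HA1 and KDM3A were 1.67-fold and 1.47-fold lower. Glycolysis had a median of -0.01 (at percentile 0.94) and a mean of 0.019, of the other sign. ENO2 was 1.53-fold lower (interval 1.37 to 1.7), PGAM1 and SLC16A1 were 1.45-fold and 1.32-fold higher and ALDOC was 1.43-fold lower. Epithelial and fibroblast markers were lower for 4 of 7 (median log2 ratio -0.40, at percentile 0.060). FN1 was 1.81-fold lower (interval 1.56 to 2.1) and KRT19, EPCAM and VIM were 1.72-fold, 1.54-fold and 1.32-fold lower. Inside the central 95% range lay the medians of glycolysis with means in place of medians, of interferon response without chromosomes 2, 9 and 10, and of core spliceosome and oxidative phosphorylation against lists matched on transcript length too. ABCG2, a drug efflux transporter, was 66.8-fold higher (interval 28.3 to 207, 15.1 against 0.227 CPM). TMPRSS15, MAGEC1, CCDC144NL-AS1 and MLLT3 were 56.7-fold, 20.6-fold, 23.2-fold and 22.7-fold higher. FSTL5, ZNF385D and its antisense gene ZNF385D-AS1 had no read in the library labelled Y19F. Against a floor of 3 counts they were at least 185-fold, at least 89.4-fold and at least 86.6-fold lower. Their lower interval bounds were 150, 72.2 and 70. MYCT1 and MS4A4A were 278-fold and 37.9-fold lower, MYCT1 with 1 read with an interval of 49.4 to 10999.

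The libraries labelled wild type, Y19D and Y19F shared 43 genes at least 2-fold from that labelled vector in 1 direction, 21 higher and 22 lower, of 10316 measured over all 4 libraries. The named examples here were chosen after their values were seen. HSPA5 was at 1405 CPM in the library labelled vector and 357, 539.8 and 494 CPM in those labelled wild type, Y19D and Y19F. The chaperone HSP90B1 was at 2443 CPM in the library labelled vector and 934, 914 and 969 CPM, and the early response factor EGR1 at 232 CPM in the library labelled vector and 80.1, 64.7 and 111 CPM. The anticoagulant TFPI was at 56 CPM in the library labelled vector and 145, 139.7 and 121 CPM, and the cell cycle inhibitor CDKN1C at 10.6 CPM in the library labelled vector and 25.5, 40.9 and 28.2 CPM. All 3 comparisons use the same vector library, which cannot be split, so part or all of the overlap may come from that library. Libraries simulated without effects shared 0 such genes at most in 100 draws. The draws had counting noise alone or the same dispersion for every gene, the median over genes. Shifts of 2-fold were therefore rare by construction, and the 0 does not exclude larger variation between lines. Pairs shared 70, 36 and 36 higher genes (wild type with Y19D, wild type with Y19F, Y19D with Y19F), where independent lists would share 2.88, 1.13 and 1.32. They shared 37, 37 and 35 lower genes against 0.996, 1.04 and 1.16. These expected numbers ignore the shared vector library, which alone can raise the overlap. Across genes, which are not independent replicates, the correlations of the log2 ratios were 0.633, 0.492 and 0.488, where unchanged libraries gave 0.50. The covariances were 0.11, 0.073 and 0.0755, against 0.0327 simulated with a dispersion of 0.0151 and 0.0033 with counting noise alone.

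Runs of neighbouring genes were shifted together between libraries in 5 of the 6 comparisons, all but Y19D against vector. Merging gave 12 runs of 43 to 188 genes on chromosomes 1, 2, 9 and 10, with medians shifted 1.22- to 1.27-fold. The 3 examples that follow were chosen after their values were seen. On chromosome 10, 188 genes between 73168166 and 133373689 (GRCh38) had a median 1.26-fold higher in the library labelled Y19F than in that labelled vector, and 90.4% of them were higher, against 49.1% of genes elsewhere. Against wild type, 142 genes on chromosome 9 between 121338988 and 137115177 had a median 1.24-fold higher in the library labelled Y19F. On chromosome 2, 97 genes between 131527675 and 190509205, among them GRB14, IFIH1 and PDK1, had a median 1.24-fold higher in the library labelled wild type than in that labelled vector.

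**Figure D4:**
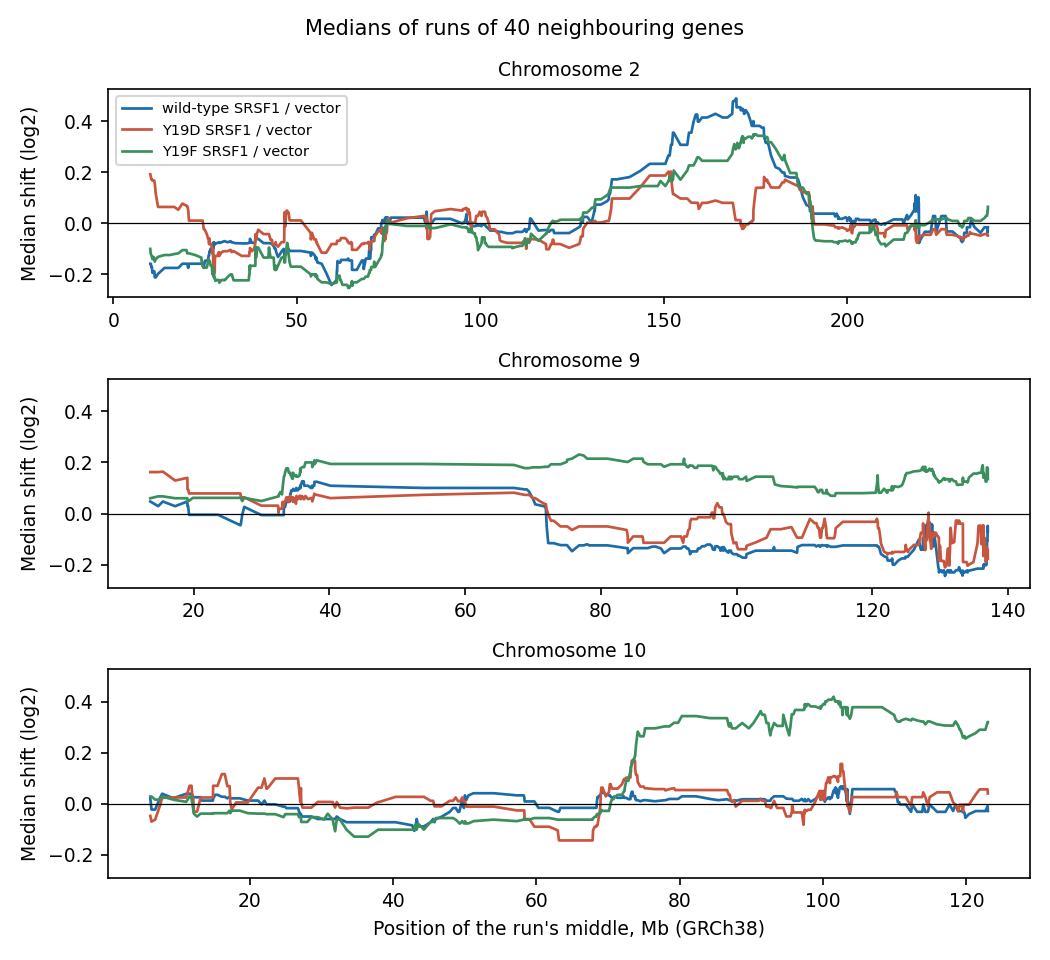
Median log2 ratio to the library labelled vector of runs of 40 neighbouring genes, less the median of all genes, along chromosomes 2, 9 and 10 by position in Mb. The green line (Y19F) is shifted upwards beyond 73168166 on chromosome 10 (a median 1.26-fold higher over 188 genes), where that labelled wild type (blue) and that labelled Y19D (red) stay lower.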

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

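Cholesterol synthesis genes stood on opposite sides of the library labelled vector in the libraries labelled with 2 constructs. Their median log2 ratio was 0.10 in the library labelled wild type (percentile 98.1 of the random lists) and -0.33 in that labelled Y19D (percentile 0.050), which put the medians 0.43 apart. SQLE was 1.8-fold higher in the library labelled wild type, and a different gene, DHCR7, was 1.59-fold lower in that labelled Y19D. Of 24 measured members, 14 were higher in the former library and 19 lower in the latter, and TM7SF2 was higher in both. The difference of the medians was not tested, since each construct has 1 library, and with means the wild type list lay inside the central range. Groups of 1 library allow no check for outlying samples.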

How the results depend on the processing

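The settings that leave out chromosomes 2, 9 and 10, that match random lists on transcript length and that rescale list medians were chosen after seeing the data. Counts of genes at 2-fold depended on the expression filter by its construction, since it sets how many genes are compared. In the order wild type, Y19D and Y19F against vector, Y19D against Y19F, Y19D against wild type and Y19F against wild type, they were 269, 304, 179, 219, 208 and 205 at a mean of 5 CPM, 473, 529, 384, 396, 380 and 394 at 1 CPM, 496, 561, 440, 420, 410 and 438 with no filter and 116, 141, 68, 78, 80 and 78 at 20 CPM. For Y19F against vector, 39.7% of these genes were higher at 5 CPM, 26.8% at 1 CPM and 24.1% with no filter. For Y19D against wild type, 53.4% were higher at 5 CPM and 63.8% at 20 CPM. The totals of both directions stayed within 1.5 times under DESeq2 size factors, total counts, a pseudocount of 0.25 CPM, the deposited fold change and all gene IDs, and without chromosomes 2, 9 and 10 (152 to 267). The directions did not all stay so. For Y19D against Y19F, 155 genes were higher and 64 lower (70.8% higher), but 243 and 60 (80.2%) with fold changes of the authors' deposited table, and 192 and 47 (80.3%) with total counts.

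SRSF1 kept its direction against the library labelled vector under each scaling and pseudocount. With total counts the log2 ratio of Y19F was -0.15, outside the counting interval of the main value of -0.10, as that scaling sets its total higher. Genes shared by the 3 libraries labelled with SRSF1 were 43 at 2-fold, 202 at 1.5-fold, 17 at 20 CPM and 40 with total counts. Of 85 list medians outside the central 95% range, 72 stayed so in the same direction with means, 76 at 1 CPM, 84 with 0.25 CPM added, 74 without the 3 chromosomes, where 6 had too few members, 80 with lists matched on length, 84 with total counts and 85 with DESeq2 size factors. In all, 22 entered the central range or turned sign under at least 1 of these. The other sign was found for the means of epithelial markers in Y19D against Y19F (-0.039) and of glycolysis in Y19F against wild type (0.019), and the median of mitochondrial genes in Y19D against Y19F with total counts (0.086), and the causes were not tested. All 444 ratios taken by the rule for named genes kept their direction with total counts and with DESeq2 size factors. Depth limits the ratios of genes with few reads in both libraries, whose counting intervals are wide. No paired analysis was possible because each group has 1 library.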

Other observations

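All tests in this part were chosen after the results they bear on were seen. Genes that were abundant in 1 library and close to absent in another are described first, with examples chosen after their values were seen. There were 41 genes with at least 150 reads in 1 library and a count lower by a factor of 30 or more in another, and 27 of them were lowest in the library labelled Y19F. In the order vector, wild type, Y19D and Y19F, the tetraspanin gene CD53 had 596, 1649, 283 and 46 reads, the oestrogen receptor gene ESR2 176, 22, 48 and 2 reads, the protocadherin gene PCDH10 162, 56, 60 and 0 reads and TRDN 357, 58, 2009 and 576 reads. BCHE, the gene of butyrylcholinesterase, had 22, 0, 204 and 27 reads.

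Many cell-type markers go against the label of the line in all 4 libraries. Of 14 markers of the fixed list that are restricted to B cells, a subset chosen after their values were seen, 7 had a row, so the authors' filter on genes does not account for their low counts. Of these, 0 reached 5 CPM in any library. RAG1, a gene of lymphocyte precursors on the fixed list but not in that subset, did so in all 4, at 5.53 to 9.25 CPM. Cells of another type mixed into B-cell precursors would leave several restricted genes abundant, so the count argues against B-cell precursors as the main cells, and a small share of them stays open. Of 17 erythroid and megakaryocyte markers with a row, 7 were at 10 CPM or more in each library. Among them were GATA1 at 186 to 235 CPM and KLF1 at 88 to 102 CPM, while 6 others were under 5 CPM in all 4. None of the erythroid and megakaryocyte markers is in the B-cell precursor list. Of 15 epithelial and fibroblast markers with a row, 7 were also at 10 CPM or more in each library. These tallies do not single out a cell type. Cells of another lineage than the label names, which may be of erythroid type, are a possibility. This stays a hypothesis, and no biological explanation was tested, since the design names no other cell type.

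SRSF1 was lower in each library labelled as carrying SRSF1 than in that labelled vector. Scaling does not account for it, since the highest of the 3 ratios to vector under 3 scalings was 0.936. A swap of labels stays open. Of the 3 swaps of vector with an SRSF1 library, 1 would put all SRSF1 libraries above the vector, that with wild type. The ratios would then be 1.7, 1.1 and 1.59. Where the vector is highest, a swap with the lowest library must give this result. The count therefore cannot decide for or against a swap, and no other value here decides whether it took place. Lower SRSF1 from the cell's own gene in cells that carry a construct was not tested, since gene counts do not separate the transcripts.

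The genes near 0 in 1 library and the shifted runs of neighbours may both come from differences between the lines and not from the constructs. Counting noise alone does not account for the genes, since the most such genes in any of 200 simulated sets of unchanged libraries was 0. Those sets had counting noise alone or the same dispersion for every gene, the median over genes. Gaps this large were therefore rare by construction, and the 0 does not exclude larger variation between lines. The largest shift of a run of 40 neighbours was 0.49 (log2), above that of each of 1000 shuffled gene orders, and the same held in 5 of 6 comparisons. In the other, Y19D against vector, 40 of 1000 shuffles were as large. A difference in copy number or clonal origin is consistent with this, while an effect of the construct cannot be told apart from it with 1 library per construct.

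The libraries labelled wild type and Y19D may share a difference from those labelled Y19F and vector. Ratios that have no library in common were correlated across genes. The ratios Y19D to vector and wild type to Y19F had a correlation of 0.207, those of wild type to vector and Y19D to Y19F 0.225, and those of Y19F to vector and Y19D to wild type 0.0192. The test as first written asked the correlation of 0.207 to be the largest of the 3 in size, and this was not met. That wording was wrong, because a difference shared by wild type and Y19D raises both larger correlations and leaves the other near 0, and the 3 are linked by algebra. Any 4 libraries have a closest pair, so with 1 library per construct this grouping cannot be told apart from chance.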
